A study of Mus musculus with 12 samples.

How the data were processed

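Leukocytes were measured one cell at a time in the synovium, the membrane that lines the joint, of male C57BL/6J mice kept on a control diet or on HFD, as the labels name the second diet. The tissue is given as synovial capsule. Live cells carrying CD45, the surface protein of all leukocytes, were sorted and captured in droplets with 10x Genomics 3' chemistry. There are 12 libraries, from the left and the right knee of 3 mice per diet, and each was made and sequenced separately, per the labels' protocols. The mice carry the numbers 4, 5 and 6 in each diet. The labels do not state whether or on which side a knee was operated, so the sides are compared as left and right only.

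The deposited files hold whole-number UMI counts per gene and cell barcode, not normalized, and the authors made them with Cell Ranger 6.1.1, per the file headers. Reads were aligned to mm10, per the submitters' processing notes. The gene annotation behind the counts is not given in the sources used here. The matrices held 86195 barcodes and 862172192 UMIs in total. The series' text states 700 to 16000 cells per mouse, and the files held 10255 to 20949 barcodes per mouse. The filter stated there, at least 500 UMIs and 550 genes and under 10% mitochondrial UMIs per cell, left 9193 to 18271 cells per mouse and 77411 in all. Those cells still held doublets. Scrublet, as run in scanpy, scored each library, and its automatic threshold marked almost none in 10 of the 12 libraries. A fixed share of 0.8% per 1000 cells, those with the highest scores, was therefore removed, which took 0.542% to 11.7% of the cells of a library. A fixed rate per cell loaded removes more cells from large libraries, so the removed share follows library size. In all, 71492 cells were kept.

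Counts per cell were scaled to 10000 and log-transformed, 3000 variable genes gave 40 principal components, and cells were joined to 20 neighbours and grouped by the Leiden method at resolution 1.0 with scanpy 1.11.5 and leidenalg 0.10.2. No integration across libraries was run. Of 34 clusters, 26 were named from fixed marker lists and joined into 13 classes, written as macrophage-like and so on. A further 8 clusters stayed unnamed because they mixed markers of several types or came mostly from 1 library, and these were compared by number. The names are rebuilt here and can differ from those of the study. A second assignment gave each cell the marker list with the highest score, and it placed 74.2% (T-cell-like) to 99.8% (plasmacytoid-dendritic-cell-like) of a class in the same class.

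Cells of one mouse are not replicates, so counts were summed. For diet, counts of a class were summed over both knees of each mouse, giving 3 mice against 3. For side, they were summed per library, with diet as a covariate. A library or mouse with fewer than 20 cells of a class was left out of that class. A class needed 2 such samples per group, and for side this was asked of each side over both diets, not of each diet, a choice made after the cell numbers were seen. Macrophage-like cells were also compared by diet within the left and the right knees, by side within each diet, and for the interaction of side and diet. HFD left knee 5 held only 15 macrophage-like cells and entered none of the macrophage fits by library. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, TMM scaling, filterByExpr), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is the fold change divided by the square root of the test's F. Values per sample are CPM, the counts of a gene scaled to the TMM-adjusted total of the tested genes of the class in that sample.

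In all, 29 lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data, when at least 5 members were tested. In macrophage-like cells 25 lists reached that number. Shares of classes among kept cells were compared with two-sided exact permutation tests, where 3 mice against 3 cannot go below p = 0.1, with adjustment over the classes and, apart from them, over the unnamed clusters. The 95% intervals of single-library shares are exact Clopper-Pearson intervals and, like all depth figures, cover counting error only. Each p-value measures the spread between mice, or for side between libraries, with both knees of a mouse treated as separate samples unless pairing is named.

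The samples and groups, the comparisons, tests, marker lists, gene lists and most alternatives were fixed before the data were examined. Genes named as changed are, per comparison, those past the threshold with a mean log2 CPM of at least 5 and no overlap between groups (for side, the same direction in at least 5 mice), leaving out ribosomal, mitochondrial and unnamed genes and antigen receptor segments. The 10 highest and 10 lowest were taken for the main macrophage comparisons and the 3 highest and 3 lowest elsewhere, with up to 4 members of smallest p per list. Identifiers and positions of the named genes come from an mm10 annotation, GENCODE M21, and all 52 were matched by the Ensembl identifier in the files. The result of 1 gene is not reported here.

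The edgeR test was tried on counts simulated from the real means and library sizes, with 200 genes changed. For macrophage-like cells by diet (10604 genes tested), 66.5% of genes changed 2-fold were recovered with 9 false calls, and 98.5% of those changed 4-fold with 10 false calls (10559 genes). For macrophage-like cells by side (9101 and 9086 genes) the shares were 79% and 100%, with 8 and 15 false calls. For the precursor-like class by diet (11447 and 11450 genes) they were 87.5% and 99%, with 11 and 8 false calls. For neutrophil-like cells by side (10196 and 10160 genes) they were 80% and 100%, with 6 and 16 false calls. With the genes of 1 list raised 1.5-fold, camera called that list in 20 of 20 draws for diet (10765 genes) and for side (9279 genes), and in 0 of 20 when nothing was raised. Lists other than the raised one, some of which share genes with it, were called 11 times over the 20 draws for diet and 13 times for side, and 1 time for side when nothing was raised. Genes were drawn independently of each other, so these draws cannot show how often camera calls lists whose genes vary together. Each gene was drawn at the trended dispersion, without a spread of its own or the structure between the real samples. Recovery and false calls in the real data may therefore be less favourable than these figures.

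No pair of libraries held identical values, and correlations of log CPM between libraries ran from 0.9376 to 0.9909. The knees of one mouse are paired by design, taken from the diet and number in the labels, and fits with the mouse as a block were run for side. For diet, mice were not taken as paired by their number, and a fit with the number as a block was run as an alternative. The alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, the blocks, doublets kept, classes by marker score, limma voom with the correlation between knees, knees thinned to equal totals, 1 fit of 4 groups, a stricter UMI minimum of 1000, a lower clustering resolution of 0.5, leukocytes only as denominator, and leaving out each mouse or library. Added after the data were seen were a term for the 3 libraries with over 10000 barcodes, the fits without HFD left knee 5 or Control right knee 5, the precursor-like clusters one at a time, 1 doublet share in every library, list tests in classes other than macrophage-like cells, and list tests with doublets kept, by marker score and without each mouse.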

Results

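Synovial leukocytes of male C57BL/6J mice were profiled by droplet single-cell RNA sequencing. The series concerns osteoarthritis, a disease of the whole joint, together with obesity, and its design crossed diet (Control Diet or HFD) with knee (left or right). Each of the 4 groups held 3 libraries, 1 from each of 3 mice. Total counts ran from 10522564 UMIs in HFD left knee 5 to 126230320 in HFD right knee 5. The number of kept cells ran from 550 in HFD left knee 5 to 11340 in HFD right knee 4, with median depths of 4842 UMIs per cell in Control right knee 5 to 11755 in HFD left knee 5. Only the right knees of Control 5, HFD 4 and HFD 5 had over 10000 barcodes each, so library size and side go together in part.

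Neutrophil-like cells, expressing S100a8, S100a9 and Retnlg, made up 45.4% of the 71492 kept cells and 30.04% to 56.49% of a library. B-cell-like cells (13.8%), monocyte-like cells (8.49%) and neutrophil- or myeloid-precursor-like cells (7.03%), called precursor-like here and led by Fcnb, Chil3, Elane and Mpo, followed. T-cell-like cells held 4.22% and macrophage-like cells, marked by C1qa, Mrc1 and Csf1r, held 2.93%, from 0.36% to 7.86% of a library. NK-cell-like (1.29%), plasmacytoid-dendritic-cell-like (1.17%), basophil-like (0.91%), ILC2-like (0.57%), conventional-dendritic-cell-like (0.56%), erythroid-like (0.37%) and eosinophil-like (0.27%) cells were rarer. Part of the B-cell-like class expressed Vpreb1, Dntt and Rag1, which act in B cell precursors, a stage usually found in bone marrow like the granule-making myeloid precursors. The cells had been sorted for CD45, so no share here is a share of the whole tissue. Among unnamed groups, cluster 13 (2.25%) expressed MHC class II genes, Retnla and Cd209a, and cluster 17 (1.78%) expressed interferon-induced genes beside neutrophil markers.

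The first comparison asked what HFD changed within each cell class, with the mouse as the replicate. In macrophage-like cells of HFD mice, the fatty acid carriers Fabp4 and Fabp5 and the triglyceride-splitting enzyme Lpl had higher values than on the control diet. Fabp4 averaged 90.2 ± 16.4 CPM on HFD and 20.7 ± 12.4 on the control diet (SD, n = 3 mice each), Fabp5 59.1 ± 28.7 and 26.9 ± 4.12, and Lpl 353.6 ± 104.5 and 151.6 ± 51.5. The groups did not overlap for any of these 3 genes, but none passed adjustment over all genes (log2 fold changes of 2.0, 1.18 and 1.23, SE 0.457, 0.298 and 0.341; edgeR adjusted p = 1.0 for each). Of 10765 genes tested, edgeR called 0 and DESeq2 called 0, with 356 and 121 genes at an unadjusted p below 0.05, and voom on the 12 libraries called 0. Without overlap between diets were 9.74% of the genes, where chance gives 10%. Fabp4 is also on the endothelial marker list and was a leading gene of unnamed cluster 26, which expressed fibroblast and endothelial markers. Lpl is also on the adipocyte marker list and was a leading gene of cluster 13. The lists of endothelial and adipocyte RNA had too few tested members here. Whether free RNA or stray cells of such groups raised these genes was not tested. The knees entered these sums unequally. Left and right knees gave 267 and 52 cells in Control 4, 337 and 189 in Control 5, and 324 and 124 in Control 6. They gave 339 and 163 in HFD 4, 15 and 212 in HFD 5, and 25 and 49 in HFD 6. Diet and side are thus mixed in part in this class. The lists below were not tested with the knees thinned to equal totals.

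As groups, 6 of the 25 lists tested in macrophage-like cells passed camera for diet, 5 higher and 1 lower on HFD, and none had a member that passed when adjusted over the list alone. The lipid-associated macrophage list, genes switched on in macrophages that take up lipid, was higher, with 20 of 27 members above 0 (median log2 fold change 0.18, mean 0.51, adjusted p = 0.000109). With an estimated correlation the adjusted p was 0.411, the list stayed past the threshold without any 1 of the 6 mice, and it did not pass when classes were set by marker score (adjusted p = 0.225). Besides Fabp4, Fabp5 and Lpl, the lectin Lgals1 had 1035 ± 20.4 CPM on HFD and 822.5 ± 85.8 on the control diet. The list of PPAR targets for fatty acid uptake, storage and oxidation was higher, with 20 of 36 members above 0 (median 0.028, adjusted p = 0.0293, and adjusted p = 0.411 with an estimated correlation). It shares Fabp4 and Fabp5 with the former list, and the nuclear receptor Pparg (0.80) and the lipid droplet protein Hilpda (0.57) had the next smallest p. This call was lost without Control 6, HFD 5 or HFD 6 (adjusted p = 0.0632, 0.104 and 0.0748) and by marker score (0.5).

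The type I interferon list, genes induced by antiviral cytokines, was lower on HFD, with 30 of 37 members below 0 (median -0.18, adjusted p = 0.00484, and adjusted p = 0.924 with an estimated correlation). Oasl2, Irgm1 and Ifit2 had log2 fold changes of -0.66, -0.54 and -1.0, none of which passed on its own, and Ifit2 lay at 0.0525 by marker score. The call was lost without Control 5 or HFD 5 (adjusted p = 0.275 and 0.232) and by marker score (0.516). Nuclear genes of the mitochondrial respiratory chain were slightly higher, with 56 of 74 above 0 (median 0.051, adjusted p = 0.00923, and adjusted p = 0.924 with an estimated correlation), among them the cytochrome c oxidase subunits Cox7b (0.30) and Cox6a1 (0.27). That call was lost without Control 4, HFD 4 or HFD 6 (adjusted p = 0.274, 0.0768 and 0.0670). The proliferation list was higher, with 25 of 34 above 0 (median 0.14, adjusted p = 0.0468, and adjusted p = 0.924 with an estimated correlation), with the tubulin-binding Stmn1 (0.34, but -0.0756 with the knees thinned to equal totals) and the cyclin Ccnb2 (0.90) as examples. It was lost without Control 4, Control 6, HFD 4 or HFD 5 (adjusted p = 0.461, 0.154, 0.128 and 0.986), with doublets kept (0.831) and with the mouse number as a block (0.107). Without HFD 5 and with doublets kept its direction turned to lower on HFD. RNA of skeletal muscle, a tissue around the joint, was also higher in these cells, with 10 of 11 members above 0 (median 0.58, adjusted p = 0.000109, and adjusted p = 0.924 with an estimated correlation), including Tnni2 (23.4 ± 12.5 against 13.2 ± 2.69 CPM) and Mylpf (0.81). Without HFD 6 this call was lost (adjusted p = 0.814), and it was lost by marker score (0.631).

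The other 19 lists did not pass for diet. NF-kB cytokines and chemokines had a median of 0.13 (adjusted p = 0.0874), Lyve1 resident macrophage genes -0.14 (0.0991), immediate early genes 0.078 (0.161) and MHC class II 0.093 (0.201). Lists of cholesterol synthesis (median -0.015, adjusted p = 0.723), LXR targets (-0.032, 0.723), lysosome (-0.048, 0.511), complement (0.022, 0.723), glycolysis (-0.034, 0.723), lining macrophages (0.18, 0.683), recruited macrophages (-0.028, 0.390) and matrix remodelling (0.0074, 0.723) did not pass either. For MHC class I the median was -0.087 while mean and test were positive (mean 0.0026, adjusted p = 0.925), and for alternative activation the median and test were negative while the mean was 0.31 (median -0.0015, adjusted p = 0.511).

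**Figure D1:**
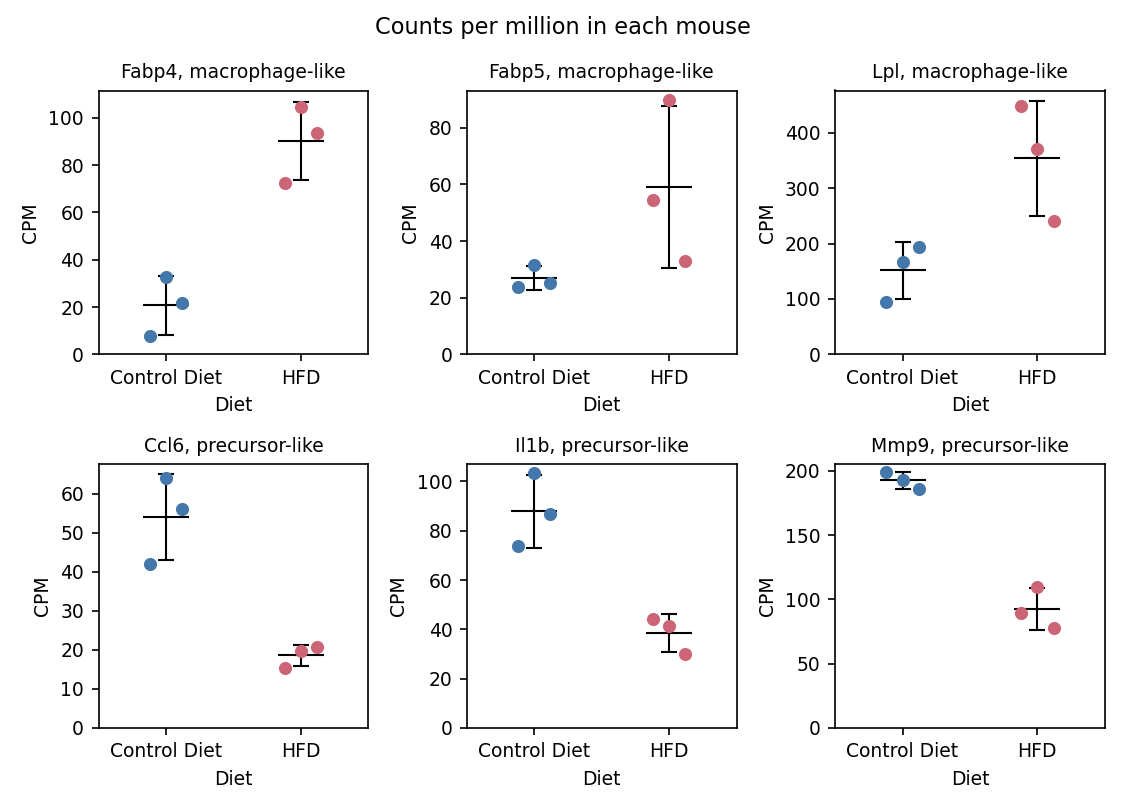
Level in CPM (vertical axes from 0) of 3 lipid genes in macrophage-like cells and 3 genes in precursor-like cells, 1 point per mouse, with mean and SD (n = 3 mice per diet). Fabp4 lay at 72.4 to 104.7 CPM on HFD and at 7.94 to 32.7 on the control diet, and Mmp9 in precursor-like cells at 77.7 to 110 on HFD and at 186 to 199 on the control diet.

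The precursor-like class held 93 of the 94 genes that edgeR called for diet, and all 93 were lower on HFD. The chemokine Ccl6 averaged 18.6 ± 2.75 CPM on HFD and 54.0 ± 11.1 on the control diet (log2 fold change -1.55, SE 0.156, edgeR adjusted p = 0.00104, n = 3 mice each). The cytokine Il1b averaged 38.4 ± 7.60 and 88.0 ± 14.9 CPM (-1.20, SE 0.160, edgeR adjusted p = 0.00803), and the gelatinase Mmp9 92.4 ± 16.4 and 192.8 ± 6.49 CPM (-1.06, SE 0.112, edgeR adjusted p = 0.000634). Chosen after their values were seen, the chemokine receptor Cxcr2 (-0.88), the calcium-binding S100a6 (-1.04), the adhesion molecule Jaml (-1.83) and Stfa2l1 (-1.74) were also among the 93, Stfa2l1 being 1 of a set of near-identical stefin copies that can share reads. In mm10 the genes Ccl6 (ENSMUSG00000018927), Il1b (ENSMUSG00000027398) and Mmp9 (ENSMUSG00000017737) span chromosome 11, 83587882 to 83593087, chromosome 2, 129364570 to 129371139, and chromosome 2, 164940780 to 164955850. All 93 genes were without overlap between the diets, as were 12.7% of the 11549 genes tested, where chance gives 10%, and 804 genes had an unadjusted p below 0.05. DESeq2 called 8 higher and 128 lower.

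Several settings lowered this count. It fell to 1 with doublets kept, to 0 by marker score, to 1 by voom on the 12 libraries, to 4 with the knees thinned to equal totals and to 3 with 1 doublet share in every library. The median log2 fold change of the genes, -1.03 as reported, was -0.55 with doublets kept (93 of 93 below 0), -0.40 by marker score (93 of 93), -0.53 when thinned (92 of 92) and -0.89 with 1 doublet share (93 of 93). The genes were picked as lower on HFD in these same mice. Their direction in these settings was therefore largely fixed by that choice and is no further evidence. The share of precursor-like cells removed as doublets was 5.01%, 12.3% and 4.10% in Control 4, 5 and 6, and 12.9%, 14.6% and 9.03% in HFD 4, 5 and 6. Without 1 mouse it was 154 (Control 4), 42 (Control 5), 42 (Control 6), 35 (HFD 4), 74 (HFD 5) and 40 (HFD 6), and without the library of Control right knee 5 it was 22, where Ccl6, Il1b and Mmp9 no longer passed (log2 fold changes of -1.06, -0.64 and -0.92, edgeR adjusted p = 0.485, 0.724 and 0.0720). Il1b was also lost without Control 6 (edgeR adjusted p = 0.0675) and with the mouse number as a block. With a term for mice that had a library of over 10000 barcodes, 68 genes were called, 63 of them among the 93.

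In basophil-like cells the matrix protease Adamts9 (chromosome 6, 92772699 to 92943492, ENSMUSG00000030022), named after its value was seen, was higher on HFD at 32.8 ± 12.6 against 5.47 ± 2.30 CPM (log2 fold change 2.34, SE 0.374, edgeR adjusted p = 0.0342, n = 3 mice each). The class gave 6 genes without Control 5 or HFD 4 and 2 without Control right knee 5. Adamts9 was lost without Control 4, Control 6 or HFD 6 (edgeR adjusted p = 0.129, 0.299 and 0.226) with doublets kept (0.107), by marker score (0.905) and by voom (0.491). In the other 11 classes besides the precursor-like and basophil-like ones edgeR called 0 genes. At an unadjusted p below 0.05 stood 711 genes in neutrophil-like, 511 in monocyte-like, 298 in conventional-dendritic-cell-like, 278 in T-cell-like, 244 in NK-cell-like, 218 in plasmacytoid-dendritic-cell-like, 141 in ILC2-like and 78 in B-cell-like cells, and 48 and 42 in eosinophil-like and erythroid-like cells with 2 mice per diet. DESeq2 called 22 in neutrophil-like and 10 in monocyte-like cells, 1 each in B-cell-like and erythroid-like cells and 0 in the rest, and voom called 2 in neutrophil-like and 1 in ILC2-like cells. Without 1 mouse edgeR called up to 24 in erythroid-like cells (Control 5, or its right knee alone) and up to 5 in eosinophil-like cells (HFD 4), fits that leave 1 mouse on 1 diet, assumed to vary like the other diet. It called 1 or 2 in B-cell-like (HFD 6), T-cell-like (HFD 4), conventional-dendritic-cell-like (HFD 4 or HFD 6), monocyte-like (Control 6) and neutrophil-like cells (HFD 6).

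Monocyte-like cells, the blood-derived relatives of macrophages, held 10.9% ± 2.85 of cells on HFD and 7.49% ± 0.134 on the control diet (SD, n = 3 mice each), with no overlap. Precursor-like cells held 6.95% ± 0.484 and 5.94% ± 0.376, and the interferon-expressing cluster 17 held 1.39% ± 0.251 and 2.42% ± 0.673. For each of these 3 the exact permutation p was 0.1, the smallest that 3 against 3 allows, and the adjusted values were 0.65, 0.65 and 0.64. Without the library of HFD left knee 5, of 550 cells, the difference between diets went from 3.40 to 1.58 percentage points for monocyte-like cells and from 1.0 to 1.60 for precursor-like cells (exact permutation p = 0.1 for both). Macrophage-like cells (2.65% ± 1.90 against 3.97% ± 0.652, exact p = 0.4, adjusted 0.9) and neutrophil-like cells (43.2% ± 3.71 against 46.4% ± 7.80, exact p = 0.7, adjusted 0.9) overlapped between diets. No share passed adjustment, and too few mice without a library of over 10000 barcodes were left to compare diets among them. Without Control 4 the neutrophil-like difference turned from -3.225 to 1.269 percentage points.

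Within single sides, the main fits of macrophage-like cells gave no gene past the threshold for diet. Fits with the mouse number as a block did call genes in left and in right knees, as given below. In left knees (2 HFD against 3 control libraries, 10856 genes) edgeR and DESeq2 each called 0, with 360 and 134 genes at an unadjusted p below 0.05, and edgeR called 1 without Control left knee 6. Without HFD left knee 4 or 6 it called 22 and 1, but 1 HFD library is then left, assumed to vary like the control libraries. In right knees (3 against 3, 8415 genes) edgeR called 0 and DESeq2 2, with 392 and 172 genes at an unadjusted p below 0.05. With a term for the large libraries edgeR called 68 in right knees, 63 of them lower on HFD, and it called 7 without Control right knee 6 and 2 without HFD right knee 6.

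The second comparison set left against right knees over both diets. In macrophage-like cells of left knees the scavenger receptor Colec12 (chromosome 18, 9707595 to 9882644, ENSMUSG00000036103) was lower, at 37.8 ± 4.28 CPM against 82.7 ± 23.8 in right knees (SD, n = 5 left and 6 right libraries), and it was lower on the left in 5 of 5 mice with both knees measured. It was the only gene called of 9279 tested (log2 fold change -1.03, SE 0.138, edgeR adjusted p = 0.00537), while DESeq2 called 3 and 487 genes had an unadjusted p below 0.05. Apoe, which carries lipid and is abundant in macrophages, had 6186 ± 1094 CPM on the left and 3833 ± 880 on the right and was higher on the left in 5 of 5 mice (0.71, SE 0.158, edgeR adjusted p = 0.3). Paired by mouse, Colec12 still passed (edgeR adjusted p = 0.0430). Its call ended without Control 4, Control 5 or HFD 4 (edgeR adjusted p = 0.0613, 0.0601 and 0.141), with doublets kept (0.113), by marker score (0.0745) and with a term for the large libraries (0.184).

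Of the 25 lists, 6 passed camera for side, 4 higher and 2 lower on the left. The lipid-associated list was higher on the left, with 19 of 27 members above 0 (median 0.26, adjusted p = 1.74e-05), 3 members passing when adjusted over the list alone, and adjusted p = 0.265 with an estimated correlation. Beside Apoe its examples are Gpnmb (2.28), the secreted matrix protein Spp1 (3.65) and the integrin Itgax (1.19), of which Spp1 and Gpnmb were higher on the left in 4 of 5 mice. Spp1 had 820.4 CPM in HFD left knee 6, from 25 cells, against 16.9 to 229.7 in the other 4 left knees, and its log2 fold change was 2.90 without HFD 6. This list stayed past the threshold without any 1 mouse. MHC class II genes, which present antigen to T cells, were higher, with 11 of 13 above 0 (median 0.24, adjusted p = 0.0156, and adjusted p = 0.553 with an estimated correlation), among them H2-DMb2 (0.71) and H2-Aa (0.26). Paired by mouse the adjusted p was 0.0549, and it was 0.0810, 0.0529, 0.198 and 0.0537 without Control 4, Control 5, HFD 4 and HFD 5. NF-kB cytokines and chemokines were higher, with 21 of 30 above 0 (median 0.12, adjusted p = 0.0162, and adjusted p = 0.553 with an estimated correlation). The neutrophil-attracting chemokines Cxcl1 (0.98) and Cxcl2 (0.46) and the NF-kB inhibitor Tnfaip3 (0.37) lay above 0, and the cytokine Osm (-0.89) below. Without HFD 4, HFD 5 or HFD 6 that list no longer passed (adjusted p = 0.156, 0.0537 and 0.0943), and by marker score it had adjusted p = 0.0555. Glycolysis and hypoxia genes were higher, with 20 of 24 above 0 (median 0.11, adjusted p = 0.0156, and adjusted p = 0.553 with an estimated correlation), such as Hk2 (0.39) and Mif (0.30). They were lost without Control 6, HFD 4 or HFD 6 (adjusted p = 0.0997, 0.0728 and 0.0943), with doublets kept (0.0784) and by marker score (0.292).

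Neutrophil transcripts within the macrophage-like class differed between sides as well. The list of neutrophil granule and activation genes was lower on the left, with 33 of 35 below 0 (median -1.03, adjusted p = 6.06e-07, and adjusted p = 0.553 with an estimated correlation), for example the arginine-modifying enzyme Padi4 (-1.42) and the decoy receptor Il1r2 (-1.41). The list of neutrophil RNA was lower too, with 13 of 13 below 0 (median -1.19, adjusted p = 0.000297, and adjusted p = 0.553 with an estimated correlation). Both stayed past the threshold without any 1 mouse, but the mean log2(CPM + 1) of the neutrophil RNA list, left minus right, was below 0 in only 3 of the 5 mice with both knees measured and above 0 in Control 4 (0.24) and HFD 6 (2.39). The same neutrophil RNA was also lower on the left in T-cell-like (median -1.19), NK-cell-like (-1.71), plasmacytoid-dendritic-cell-like (-1.63) and basophil-like cells (-1.49), which should lack it, less so in B-cell-like cells (-0.544) and hardly in conventional-dendritic-cell-like cells (-0.0421).

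The other 19 lists did not pass for side. Lyve1 resident macrophage genes had a median of -0.0076 (adjusted p = 0.0838, 1 member when adjusted over the list alone), with the phosphatidylserine receptor Timd4 (-0.89), the haemoglobin scavenger receptor Cd163 (-0.57) and Lyve1 (-0.82) below 0. Lining macrophage genes had a median of -0.13 (adjusted p = 0.0838), with Sparc at -1.49 and Vsig4 at -1.01. Among the lists with members that passed in this way were also PPAR targets (median -0.027, adjusted p = 0.597, 3 members) and LXR targets (0.070, 0.189, 1 member). MHC class I (0.073, 0.0588), lysosome (0.075, 0.0588), cytotoxic genes (0.32, 0.0588), T cell activation genes (0.11, 0.0838), immediate early genes (0.062, 0.131) and type I interferon genes (0.056, 0.404) had medians above 0, and complement genes (-0.11, 0.200), recruited macrophage genes (-0.24, 0.311) and muscle RNA (-0.30, 0.179) below 0. For proliferation, median (-0.072) and mean (-0.10) were negative and the test positive (adjusted p = 0.329), and for the respiratory chain the median was -0.0016 while mean and test were positive (mean 0.0057, adjusted p = 0.597).

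Outside macrophage-like cells, ILC2-like cells, innate lymphocytes that make type 2 cytokines, had a higher level of the cytoskeletal linker Dst on the left, named after its value was seen. It had 106.7 ± 10.6 CPM in 4 left and 28.8 ± 18.3 in 5 right libraries and was higher on the left in 3 of 3 mice (log2 fold change 1.89, SE 0.342, edgeR adjusted p = 0.0268). DESeq2 called 0 genes there, and pairing by mouse raised the edgeR count from 1 to 35. The Dst call was lost by DESeq2 (adjusted p = 0.136), by marker score (0.191) and without each mouse but HFD 6, with edgeR adjusted p = 0.0825, 0.225, 0.123, 0.394 and 0.0828 without Control 4, 5, 6, HFD 4 and 5, and 0.0834 without Control right knee 5. In the other 9 classes edgeR called 0 genes, with an unadjusted p below 0.05 for 650 genes in T-cell-like, 618 in precursor-like, 404 in basophil-like, 378 in neutrophil-like, 286 in monocyte-like, 236 in plasmacytoid-dendritic-cell-like, 231 in NK-cell-like, 148 in conventional-dendritic-cell-like and 146 in B-cell-like cells. DESeq2 called 3 in basophil-like and 1 in T-cell-like cells and 0 in the rest. Paired by mouse, edgeR called 9 in plasmacytoid-dendritic-cell-like, 4 in basophil-like, 3 in NK-cell-like, 2 in precursor-like and 1 each in B-cell-like and T-cell-like cells. Without HFD 6 the count over all classes rose from 2 to 92, 79 of them higher on the left, with 83 in T-cell-like, 6 in basophil-like and 2 in ILC2-like cells. Without Control 6 NK-cell-like cells gave 2, and without HFD 5 basophil-like cells gave 1.

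Macrophage-like cells held 4.79% ± 2.76 of cells in left knees and 1.82% ± 0.574 in right knees (SD, n = 6 libraries each) and were more frequent on the left in 5 of 6 mice, HFD 6 being the exception. Precursor-like cells held 5.32% ± 1.45 on the left and 7.57% ± 1.41 on the right and were less frequent on the left in 5 of 6 mice. The exact permutation p was 0.0433 and 0.0238, but with adjustment over the classes both were 0.272, and with signs flipped within mice the exact p was 0.0938 for both. Among the 9 libraries of at most 10000 barcodes, macrophage-like cells held 4.79% ± 2.76 in 6 left and 1.90% ± 0.834 in 3 right knees (exact p = 0.167) and precursor-like cells 5.33% ± 1.45 and 6.66% ± 0.752 (exact p = 0.143). Erythroid-like cells (0.142% ± 0.145 against 0.57% ± 0.545, exact p = 0.0628, adjusted 0.272) were lower on the left in 6 of 6 mice. Neutrophil-like cells (43.2% ± 8.04 against 46.4% ± 6.95, exact p = 0.487, adjusted 0.633) and cluster 13 (2.96% ± 1.69 against 1.77% ± 0.289, exact p = 0.119, adjusted 0.238) differed by less than the spread between libraries.

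**Figure D2:**
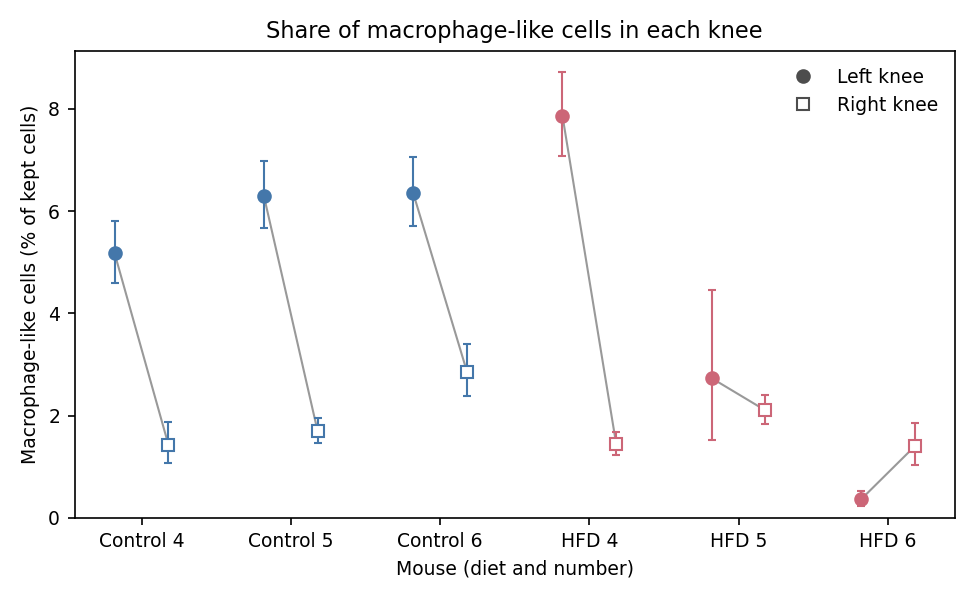
Macrophage-like cells in percent of the kept cells (vertical axis) in the left and right knee of each mouse (horizontal axis), lines joining the 2 knees of a mouse and bars giving exact 95% intervals for counting error. The left knee lies above the right in 5 of 6 mice, from 7.86% against 1.44% in HFD 4 to 2.73% against 2.10% in HFD 5, and below it in HFD 6 at 0.36% against 1.40%.

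Side was then compared within each diet. On HFD, macrophage-like cells of left knees had more of the monocyte-attracting chemokine Ccl12 (93.7 ± 17.7 against 15.4 ± 8.53 CPM, log2 fold change 2.50, SE 0.312, edgeR adjusted p = 0.00434) and of the actin-binding thymosin Tmsb10 (742.2 ± 73.1 against 265.2 ± 69.3 CPM, 1.48, SE 0.215, edgeR adjusted p = 0.0137), in 2 left and 3 right libraries. In mm10, Ccl12 (ENSMUSG00000035352) spans chromosome 11, 82101845 to 82103400, and Tmsb10 (ENSMUSG00000079523) chromosome 6, 72957347 to 72958748. These were the 2 genes called of 8394, with 245 at an unadjusted p below 0.05, and DESeq2 called 4, as did edgeR paired by mouse. The count was 0 with doublets kept, with all libraries in 1 fit, and without HFD right knee 4 or 5, and it was 4 without HFD right knee 6. Without HFD left knee 4 or 6 it was 21 and 7, with 1 left library remaining, assumed to vary like the right ones. Ccl12 did not pass without HFD left knee 4, HFD right knee 4 or HFD right knee 5 (edgeR adjusted p = 0.1, 0.211 and 0.0563), nor Tmsb10 without HFD right knee 4, 5 or 6 (edgeR adjusted p = 0.259, 0.0615 and 0.0512) or by marker score (1.0).

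On the control diet (3 left and 3 right libraries, 9608 genes) edgeR called 0 genes, with 634 at an unadjusted p below 0.05, DESeq2 called 4 higher and 34 lower on the left with 345 at that p, and edgeR paired by mouse called 5 higher and 29 lower. Without Control left knee 6 or Control right knee 6 edgeR called 2. Whether the difference between sides itself depended on diet was tested by the interaction. Of 9643 genes edgeR called 0 and DESeq2 1, with 376 and 197 at an unadjusted p below 0.05, edgeR paired by mouse called 2, and without HFD 4, with 1 HFD left library remaining and assumed to vary like the other groups, it called 5. Left minus right, macrophage-like shares differed by 2.0 ± 3.92 percentage points on HFD and 3.95 ± 0.58 on the control diet (SD, n = 3 mice each, exact permutation p = 0.4, adjusted 0.867). Neutrophil-like shares differed by -9.94 ± 8.17 and 3.59 ± 5.60 points (exact permutation p = 0.2, adjusted 0.867).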

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

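Chosen only after the results were seen were the tests on doublets removed at unequal rates, on the largest precursor-like cluster, on the splits of mice for the 93 genes, on macrophage-like cells per lymphocyte, on exchanged knees of HFD 6 and on neutrophil shares. After its value was seen, the bound for doublets removed at unequal rates was also tightened to ask for the spread of the genes.

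In HFD left knee 5, the smallest library, monocyte-like cells held 19.45% against 11.13% in the next left knee, and cluster 30 held 2% against 0.72%. In Control right knee 5, cluster 31 held 3.46% against 0.67% in the next right knee. Each was a single library far from the other 5 of its side, and 3 of 50 groups tested stood apart in this way where 2.5 would by chance, at 1 in 20. Left minus right, the B-cell-like share was positive in all HFD mice and negative in all control mice, by 3.38 ± 2.0 against -4.05 ± 4.72 percentage points, a difference of 7.434 with an exact permutation p of 0.1 (adjusted 0.867). It was 1 of 21 items with such opposite signs.

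The 93 genes lower on HFD in precursor-like cells had a median log2 fold change of -1.03 (quartiles -1.39 and -0.62). Free neutrophil RNA was looked for in 5 other classes, where 40 (NK-cell-like) to 83 (B-cell-like) of the 93 genes could be tested. Their medians ran from -0.0877 in basophil-like to 0.219 in B-cell-like cells, with -0.0126 in the middle, so no marked drop was seen there. But only 5 of the 93 genes are on the fixed neutrophil lists. The other classes may express the rest themselves, which could hide free RNA, so this explanation stays open. Doublets stay open, because with doublets kept the median was -0.551 (-0.76 to -0.41) and with 1 doublet share removed in every library -0.888 (-1.19 to -0.49), neither clear of its bound by the spread of the genes. For the second of these tests the bound written beforehand asked for the median alone, which met it. The spread of the genes was a further condition there. A mix of the precursor-like clusters is argued against as the whole cause, since within cluster 15, which held 36% to 49.4% of the class on the control diet and 42.8% to 47.2% on HFD, the median was -1.23 with an upper quartile of -0.705, but it stays open as a part, with medians of -0.676 in cluster 23 and -0.443 in cluster 29, the latter under 0.5 of the class median. A later maturation state of precursors on the control diet may remain as a biological explanation, which was not tested.

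The higher macrophage-like share in left knees could come from dilution by marrow-type cells in right knees. This stays open, since macrophage-like cells per 100 T-cell-like, NK-cell-like and ILC2-like cells were 66 ± 32.5 in left and 32.1 ± 4.8 in right knees, 2.06-fold and higher on the left in 5 of 6 mice, with an exact permutation p of 0.039 between libraries (n = 6 each) but an exact p of 0.0625 with signs flipped within mice. In HFD 6, the mouse that went the other way, 6 of 6 cell groups typical of tissue were lower in the left knee, against 0 to 2 of 6 in the other mice. An exchange of its knees stays open too. In its macrophage-like cells Colec12 had 40.4 CPM on the left and 120.8 on the right and Apoe 5572 and 4596, the same direction as in the other mice. Both genes were picked from data that include this mouse, so this cannot decide. The list of neutrophil RNA, fixed beforehand, lay at 2.39 left minus right in HFD 6. It lay at 0.241 in Control 4, -2.21 in Control 5, -2.98 in Control 6 and -1.1 in HFD 4. The labels were kept as given. An effect of a procedure on 1 knee was not tested, since the labels name none.

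The lower neutrophil RNA in left-knee macrophage-like cells is consistent with free neutrophil RNA, because its list had a median of -1.34 over 6 classes that should lack it, from -1.71 in NK-cell-like to -0.0421 in conventional-dendritic-cell-like cells. Doublets of macrophages and neutrophils stay open. The median was -0.914 with doublets kept and -1.19 without them, so keeping them did not enlarge the difference. But doublets that the score missed are in both sets, and the removed share follows library size. Removing 1 doublet share in every library was not tried for side. The share of neutrophils in the library stays open, though few values go with it. In the 3 mice with a lower list on the left, the share left minus right was 3.93 points in Control 5, 9.01 in Control 6 and -17.9 in HFD 4. In Control 4 and HFD 6, where the list lay higher on the left, the share was lower there (-2.17 and -1.54 points). List and share thus ran the same way only in HFD 4. Left minus right the list lay at 0.241 in Control 4, -2.21 in Control 5, -2.98 in Control 6, -1.1 in HFD 4 and 2.39 in HFD 6, so its direction was not shared by all mice. No biological explanation was tested.

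The splits of the 6 mice into 3 and 3 number 10, the real one included, too few for a share under 0.05. For the 93 genes of the precursor-like class 1 of 10 splits, the real one, gave as many, with 3 as the highest other. Over all classes 4 of 10 gave at least the real 94, with 958 as the highest, in the split of Control 5, HFD 4 and HFD 5, the mice with a library of over 10000 barcodes, from the rest, which points to a structure of the samples. Of these, 315 are from neutrophil-like cells and 553 from erythroid-like cells, where it sets Control 5 and HFD 5 against Control 6 and HFD 6, as does 1 other split that also gave 553 there and does not part the mice by library size. With a term for the large libraries the precursor-like class gave 68 genes. For basophil-like cells 4 of 10 splits gave at least the real 1 (highest other 20), and for macrophage-like lists by diet 8 of 10 gave at least the real 6 (highest other 15), and both highest counts came from that same split. The real count was 0 for macrophage-like genes by diet (highest other 7), by diet in right knees (4) and by side on the control diet (2), which all 10 of 10 splits reach. For side, 4 of 30 splits gave at least the real 1 gene in macrophage-like cells (highest other 4), 8 of 30 the real 1 in ILC2-like cells (33), 12 of 30 the real 2 over all classes (240) and 20 of 30 the real 6 lists (13), so chance cannot be excluded for any of these. Among 32 splits that part the knees of every mouse, 3 reached the macrophage-like count (highest other 2) and 6 the ILC2-like count (3).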

How the results depend on the processing

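Added after the data were seen were the term for large libraries, the fits without HFD left knee 5 or Control right knee 5, the precursor-like clusters alone, and list tests with doublets kept, by marker score and without each mouse. The cause was not tested for any change below, save that leaving out samples or thinning lowers the depth. Genes past the threshold for diet over all classes numbered 94, and 173 by DESeq2 (93 shared), 359 with no low-count filter, 445 with the mouse number as a block, 1 with doublets kept, 4 by marker score, 4 by voom, 6 with the knees thinned to equal totals, and 46 (without HFD 6) to 154 (without Control 4). In the precursor-like class, 93 became 248 with no filter, 232 with the block, 1 with doublets kept, 0 by marker score, 1 by voom, 4 when thinned, and 22 to 154 with 1 mouse or library left out. Alone, cluster 15 gave 6 genes higher and 39 lower, cluster 23 gave 5 and 25, and cluster 29 gave 0 and 2. In macrophage-like cells, 0 became 1 with no filter, 1 when thinned and 1 with the term for large libraries. Whether mouse numbers pair mice across diets stays uncertain. Deviations of mice with 1 number from their diet means had correlations of 0.227, 0.245 and 0.379 in B-cell-like cells, all over 0.1, but 0.0305, 0.142 and 0.152 in macrophage-like, -0.039, 0.362 and 0.544 in neutrophil-like and -0.09, 0.112 and 0.0386 in monocyte-like cells. Of 6 mice, 6, 5, 3 and 3 correlated best with their own number in these classes, a hint from the data and not from the design. Without every pair over 0.1 in every class the numbers were not taken as pairs. The block gave 2 genes instead of 0 in B-cell-like cells and ended the call of Il1b (edgeR adjusted p = 0.0535) and of the proliferation list (0.107).

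For side over all classes tested for it, 2 became 7 by DESeq2, 628 with no filter, 56 paired by mouse, 11 with doublets kept, 6 by marker score, 11 with the term for large libraries, and 0 to 92 without 1 mouse. In macrophage-like cells, 1 became 3 by DESeq2, 205 with no filter, 0 with doublets kept, 0 by marker score, 0 with that term, and 0 to 1 without 1 mouse. In precursor-like cells, 0 became 1 with no filter and 2 paired by mouse. On the control diet, 0 became 38 by DESeq2, 140 with no filter, 34 paired by mouse, 1 by marker score, and 0 to 2 without 1 library. On HFD, 2 became 4 by DESeq2, 19 with no filter, 4 paired by mouse, 0 with doublets kept, 18 with that term, 0 in 1 fit of 4 groups, and 0 to 21. Pairing by mouse also ended the call of the MHC class II list in macrophage-like cells (camera adjusted p = 0.0549, from 0.0156). It changed no other call of a side result named in the text.

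For diet in left knees, 0 became 34 with no filter, 39 with the block, and 0 to 22 without 1 library (22 and, for side on HFD, 21 with 1 HFD left library remaining, assumed to vary like the other group). In right knees, 0 became 2 by DESeq2, 1 with RLE scaling, 64 with no filter, 27 with the block, 68 with the term for large libraries, and 0 to 7. For the interaction, 0 became 1 by DESeq2, 27 with no filter, 2 paired by mouse, 5 with that term, and 0 to 5. Of 6 lists by diet and 6 by side, 0 and 0 passed with an estimated correlation, and those by side became 11 by marker score and 4 to 14 without 1 mouse. No share passed its threshold under any alternative. The neutrophil-like share by diet turned from -3.225 to 1.269 without Control 4, the range without 1 mouse being -5.749 to 1.269, Ifit2 from -1.0 to 0.0525 by marker score and Stmn1 from 0.34 to -0.0756 when thinned. Of 839 values of named genes, 751 kept direction and side of the threshold, 66 lost and 20 gained their call and 2 reversed. Many of these genes did not pass in the main fit, so keeping their side of the threshold shows little. Of 319 counts of 1 class, those of macrophage-like and precursor-like cells left out, 238 stayed equal or close to the main count and 81 moved. Since no share passed, the 174 of 175 shares that stayed the same kept their direction only, and 1 reversed. By diet, eosinophil-like cells had no voom or block value and erythroid-like cells none by voom, and the term for large libraries had none in left knees. Rare classes and the 15 macrophage-like cells of HFD left knee 5 limit what depth can show.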

Other observations

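All list tests in this part were added to the planned tests, which covered macrophage-like cells, while the lists themselves were not changed. On HFD the type I interferon list, genes of the antiviral response, was lower in monocyte-like cells (36 of 37 members below 0, median -0.29, camera adjusted p = 1.14e-18), B-cell-like cells (31 of 34, -0.41, 5.45e-19), conventional-dendritic-cell-like cells (19 of 20, -0.55, 7.28e-15), neutrophil-like cells (32 of 35, -0.25, 5.92e-09), plasmacytoid-dendritic-cell-like cells (20 of 21, -0.29, 5.81e-07), NK-cell-like cells (14 of 18, -0.27, 2.59e-05) and basophil-like cells (16 of 20, -0.22, 0.0147). With an estimated correlation the adjusted p was 0.234, 0.282, 0.127, 0.42, 0.518, 0.919 and 0.535 in the same order. When adjusted over the list alone, 8 members passed in monocyte-like, 7 in conventional-dendritic-cell-like, 1 each in B-cell-like and plasmacytoid-dendritic-cell-like cells and 0 in the other 3. T-cell-like (median -0.074, adjusted p = 0.124), ILC2-like (0.018, 0.39) and erythroid-like cells (-0.24, 0.209) did not pass. Precursor-like and eosinophil-like cells are not described for this list. None of these calls was tried without single mice. In macrophage-like cells the call of this list was lost without Control 5 or HFD 5 (camera adjusted p = 0.275 and 0.232). For macrophage-like lists by diet, 8 of 10 splits of the mice gave at least the real number of passing lists. The share of cluster 17, led by the interferon-induced Rsad2, Ifit1 and Isg15, was also lower on HFD in the values given above without passing adjustment.

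In precursor-like cells 11 of 26 lists passed for diet. NF-kB cytokines and chemokines were lower (20 of 21 below 0, median -0.47, adjusted p = 4.59e-19, and adjusted p = 0.0552 with an estimated correlation), as were matrix remodelling genes (15 of 18, -0.21, 3.14e-13), the only list to hold with an estimated correlation (adjusted p = 0.0319). Over the list alone 9 and 7 members passed. Il1b belongs to the former list and Mmp9 to the latter, both among the genes called in this class. These lists were not tested again with doublets kept, by marker score or with the knees thinned, settings where far fewer genes of this class were called. Nuclear respiratory chain genes were higher (71 of 74 above 0, median 0.11, adjusted p = 7.96e-09, and adjusted p = 0.576 with an estimated correlation). Proliferation genes were higher on HFD in conventional-dendritic-cell-like (37 of 38, 0.62, 9.87e-26), T-cell-like (32 of 37, 0.39, 4.91e-12), monocyte-like (37 of 38, 0.38, 1.18e-10) and neutrophil-like cells (36 of 38, 0.33, 0.000358), with adjusted p = 0.259, 0.654, 0.453 and 0.646 with an estimated correlation. They were also higher in erythroid-like (0.35, 0.00405) and precursor-like cells (0.053, 0.0113) and lower in B-cell-like cells (27 of 38 below 0, -0.087, 0.00013), with adjusted p = 0.867, 0.74 and 0.833 with an estimated correlation. Of these lists only that of conventional-dendritic-cell-like cells had members that passed when adjusted over the list alone, 5 of 38. In eosinophil-like cells most tested proliferation genes lay below 0 on HFD, none past the threshold on its own. The list is not described for NK-cell-like, plasmacytoid-dendritic-cell-like, basophil-like and ILC2-like cells, so no rise across all classes is claimed. Between sides, NF-kB genes were higher on the left in basophil-like (19 of 20, 0.46, 6.97e-10), neutrophil-like (25 of 26, 0.29, 3.08e-10) and monocyte-like cells (25 of 28, 0.21, 1.27e-05), with adjusted p = 0.112, 0.358 and 0.675 with an estimated correlation, and 6, 0 and 0 members adjusted over the list alone. The lists of different classes come from the same mice and are not independent of each other.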
